A study of Mus musculus with 6 samples.

How the data were processed

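The 6 libraries are Omni-ATAC libraries of 50000 cultured bone marrow macrophages each, sequenced on 4 lanes as paired-end reads of 125 bp, per the labels' protocols. The submitters' processing notes name Trim Galore 0.4.4, cutadapt 1.14, Bowtie2 2.2.6, SAMtools, Picard, MACS2 2.1.0.20140616 and the build mm10, without roles or order. One MACS2 broad peak list was deposited per library, so replicates were not pooled. Each deposited peak carries a score, the whole part of 10 times its −log10 q, a fold enrichment (a ratio over the local background of that library), and its −log10 p and −log10 q as the authors' caller gave them. The lowest deposited −log10 q lay just over 1 in each library. These values belong to single peaks of single libraries and were used only to rank or filter peaks within a list. Steps such as the removal of duplicate reads, the shift of read ends for the transposase and masking of problem regions are not given in the sources used here. The lists held no peak on the mitochondrial chromosome. Read depth is unknown, so a library with more reads can have a longer list and wider peaks, and absence of a peak means only that none was called.

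Groups and replicate numbers came from the labels (3 young and 3 old libraries). Gene positions came from the RefSeq genes of GRCm38.p6, which shares its primary chromosomes with mm10; 21631 protein-coding genes on chromosomes 1 to 19 and X were used. The table gives gene spans without strand, exons or start sites, so start sites were replaced by both gene ends, the genomic distribution has 3 classes (within 1 kb of a gene end, gene body, elsewhere), and exons and introns were not separated. Motif content was not analysed here, since no genome sequence was used. Other chromosomes and contigs stayed out of the comparisons.

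For each gene locus, the gene plus 10 kb on each side, the base pairs covered by peaks were summed per library, divided by the library's sum over all loci and rescaled to the mean sum. Loci with a mean of 500 bp or more were tested with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes) on log2(bp + 200), old minus young, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale and understate changes of sparsely covered loci. Neighbouring and overlapping genes share peaks, so their values are not independent. Cxcl13 fell below the filter and its values come from the fit without it. The 43 gene lists were tested with limma camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation; older symbols that did not match a protein-coding gene were left out. Overlap was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; regions are merged peaks that overlap by 1 bp or more. Figures were drawn with matplotlib 3.10.9. Group means of single values were compared with exact permutation tests, whose smallest two-sided p is 0.10.

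Genes were named by a rule set before the data were examined: Cxcl13, Cxcr5, Adgre1 and Siglec1 in any case; 8 called loci per direction with the largest change whose old values all lie on one side of the young values; 6 genes per direction with age-only gene-end peaks that rank best in their weakest library; and the members of each described list with the smallest p. The 8 lists described in detail, and the limit of 2 members in each, were settled after the values were seen, from 16 lists considered at first; all 43 were tested. Gene models and clustered near-identical copies were left out of the middle parts; which gene families count as such copies (Gbp genes among them) was settled after the called loci were seen. Regions followed the same ranking, 3 per direction. A gene outside the rule is named only where it is one of a few called members, is called in both kinds of list, or stands for a cell type; these were chosen after the values were seen. The 3 old values lay apart from the 3 young values at 17.0% of loci on the deposited lists, where chance gives 10%.

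Alternatives fixed before the data were examined were a −log10 q of at least 2 or 5, equal-length lists of 50000 peaks, other overlap and gene-end windows, another pseudocount, no scaling, quantile normalization, no filter, a replicate block and leaving out each library. Because equal-length lists changed the balance of directions, they are given beside the deposited lists. Those added after the data were seen were 5 kb around both gene ends in place of the gene start, the library's total covered length as a covariate, and the block and left-out libraries on equal-length lists. The locus test was tested on simulated data with 200 changed loci: for old against young on the 16952 loci of the deposited lists it recovered 33% of log2 changes of 0.5, 90% of 1 and 99% of 2, and on the 14395 loci of the equal-length lists 0%, 67.5% and 93%. It also called 1, 4 and 7 unchanged loci on the former and 0, 6 and 7 on the latter. Each locus and library was drawn independently, without signal shared across a library or peaks shared by neighbouring genes. Recovery may therefore be lower in the real data. The overlap step recovered 200 of 200 planted age-only regions among 403801, which checks the counting only.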

Results

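Open chromatin was mapped by ATAC-seq, which marks accessible DNA by the insertions of a transposase, in macrophages grown from the bone marrow of BALB/c mice of 2 ages. Young mice were 3 weeks old and old mice were over 78 weeks old, with 3 libraries per age and 50000 cells per library. The cells were adherent marrow cells expanded in culture and typed as F4/80+CD169+; F4/80 is the product of Adgre1 and CD169 that of Siglec1. The title of the series ties the age of the marrow to B-cell leukaemia through the chemokine CXCL13 and its receptor CXCR5, so the comparison asks which loci differ in accessibility between young and old macrophages. Each library has its own list of peaks. The young lists held 243924, 223018 and 254410 peaks covering 62.2, 52.4 and 66.1 Mb, and the old lists 245667, 227978 and 215947 peaks covering 63.8, 48.2 and 49.0 Mb. The mean was 240451 ± 15982 peaks in young and 229864 ± 14949 in old (SD, n = 3), and this difference was smaller than the spread between libraries (two-sided exact permutation test, p = 0.50; the smallest p that 3 against 3 allows is 0.10). Read numbers were not used here and the depth is unknown. The labels do not say whether replicates are separate mice or cultures, so p-values measure only the spread between these libraries, which may be technical.

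Cxcl13, which codes for the chemokine that draws CXCR5-bearing B cells, lies on chromosome 5 from 95956939 to 95961068 (mm10). No library had a peak inside the gene, and small peaks lay within 10 kb of it at both ages. The most regular of them, at 95965052 to 95965201 in young replicate 1, overlapped a peak in the other 2 young libraries and in old replicates 1 and 3. Within the locus, taken as the gene and 10 kb on each side, peaks covered 237, 231 and 219 bp in young replicates 1, 2 and 3 and 359, 46 and 173 bp in old replicates 1, 2 and 3. Its covered length did not differ by limma between ages in a fit of all loci without a filter (log2 change -0.16, SE 0.29, adjusted p = 0.97), and the change was 0.13 without old replicate 2. When peaks needed a −log10 q of 2 or more, the locus kept peaks in all 3 young libraries and in old replicate 1 alone (log2 change -0.77, SE 0.28, unadjusted p = 0.0483, adjusted p = 0.49). The locus held no peak among the 50000 strongest peaks of any library.

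**Figure D1:**
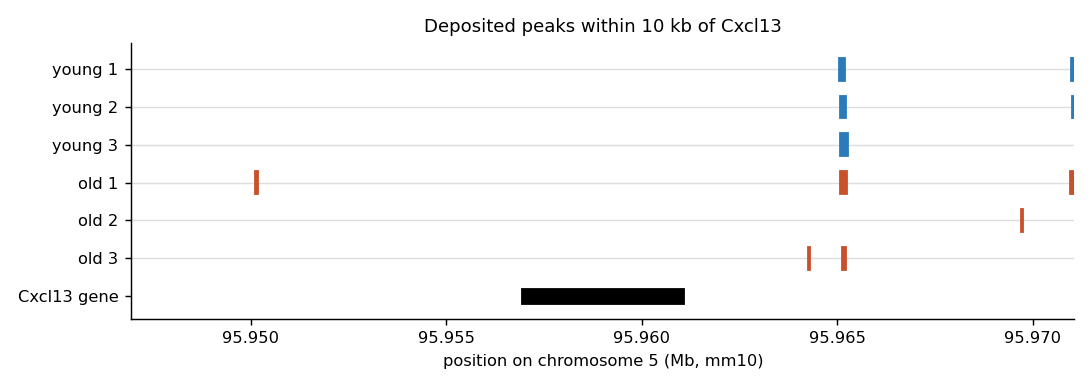
Deposited peaks (boxes, to scale) within 10 kb of Cxcl13 in each library, against the position on chromosome 5 in Mb; young libraries are blue, old libraries orange and the black bar is the gene. The peaks lie outside the gene, and old replicate 2 has a single box of 46 bp.

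Cxcr5 (chromosome 9, 44511787 to 44526444), which codes for the CXCL13 receptor, was covered over 1859 ± 269 bp in young and 1836 ± 152 bp in old libraries (SD, n = 3, scaled to the mean library total; log2 change -0.01, SE 0.12, adjusted p = 0.99). Both genes behind the macrophage phenotype held peaks at both ages, which by itself does not mark the cell type. The median over all protein-coding genes was 1977 bp in young and 1974 bp in old, above the values of Adgre1. Adgre1 (chromosome 17, 57358581 to 57483529) had 1104 ± 146 bp in young and 1265 ± 164 bp in old (log2 change 0.17, SE 0.15, adjusted p = 0.69). Siglec1 (chromosome 2, 131067801 to 131086778) had 2288 ± 383 bp in young and 2462 ± 204 bp in old (log2 change 0.11, SE 0.11, adjusted p = 0.77). None of these 3 loci passed the test. Directions depended on the list: Siglec1 had a log2 change of -0.73 (SE 0.34, adjusted p = 0.38) among the strongest 50000 peaks. Adgre1 had 415 ± 96.3 bp in young and 379 ± 44.5 bp in old there, and lay below the filter.

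Across 16952 gene loci, 65 were covered more widely and 98 less widely in old libraries at an adjusted p under 0.05 (limma on log2 covered length + 200 bp). The loci wider in old with the largest changes were led by Grid1, a glutamate receptor delta subunit gene (chromosome 14, 34820003 to 35583387), which went from 1177 ± 34.7 bp in young to 4200 ± 936 bp in old (log2 change 1.66, SE 0.13, adjusted p = 3.38e-06). Ntrk3, the neurotrophin-3 receptor gene (chromosome 7, 78179986 to 78581034), went from 868 ± 130 to 2304 ± 248 bp (log2 change 1.23, SE 0.13, adjusted p = 0.000167). Tbx5 and Pax7, genes of developmental transcription factors, had log2 changes of 1.23 (SE 0.18) and 0.98 (SE 0.19). Hs3st4, a heparan sulfate sulfotransferase gene on chromosome 7 (123982366 to 124398989), had 0.96 (SE 0.12), and Atp13a4 and Slc22a14 had 1.16 (SE 0.17) and 1.13 (SE 0.24). Adcyap1r1, the receptor gene of the neuropeptide PACAP, went from 314 ± 151 to 925 ± 259 bp. The adjusted limma p of these last 6 lay between 0.000591 and 0.0367. In each of these loci the 3 old values lay above the 3 young values, as the naming rule required. Stab2, a scavenger receptor gene of the efferocytosis list, was also wider (log2 change 0.73, SE 0.09, adjusted p = 0.000679).

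The narrowest loci in old relative to young were Dbx2, a homeobox gene on chromosome 15 (95623563 to 95654771), and Adamts18, a secreted metalloprotease gene on chromosome 8 (113697123 to 113849343). Dbx2 went from 987 ± 196 to 131 ± 85.9 bp (log2 change -1.87, SE 0.28, adjusted p = 0.00221), and Adamts18 from 2504 ± 632 to 543 ± 85.3 bp (log2 change -1.84, SE 0.17, adjusted p = 3.23e-05). Nell2, which lies next to Dbx2, had a log2 change of -1.38 (SE 0.27). Itgbl1, Mgat4c, Asxl3 and Ehf had log2 changes of -1.33 (SE 0.29), -1.20 (SE 0.15), -1.07 (SE 0.15) and -1.07 (SE 0.25), and Dpyd, which codes for an enzyme of pyrimidine breakdown, had -1.03 (SE 0.14). Their adjusted limma p lay between 0.000679 and 0.0481. Called loci were long: the median gene was 96.5 kb among loci wider in old and 125 kb among loci narrower in old, against 22.5 kb for all tested loci. The count rests on the scaling to the library total: without it 2 loci were wider and 13 narrower, with the median of all loci at -0.14. With peaks of −log10 q of 5 or more there were 3 and 6. With total covered length as a covariate there were 32 and 19, 38 of them among the 163 called loci. All 163 kept their direction there, and their median change in the direction of the call went from 0.54 to 0.51, with Grid1 at 1.61, Atp13a4 at 1.26, Adamts18 at -1.81 and Dbx2 at -1.65. Without the 500 bp filter, 0 were wider and 4 narrower (limma, 2217 at an unadjusted p under 0.05), and none of these 16 named loci wider or narrower in old kept an adjusted p under 0.05 there. Without young replicate 1 there were 16 wider and 15 narrower loci, without young replicate 2 38 and 87, and without young replicate 3 42 and 22. The numbers were, without old replicate 1, 92 and 260, without old replicate 2 26 and 49, and without old replicate 3 27 and 30.

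**Figure D2:**
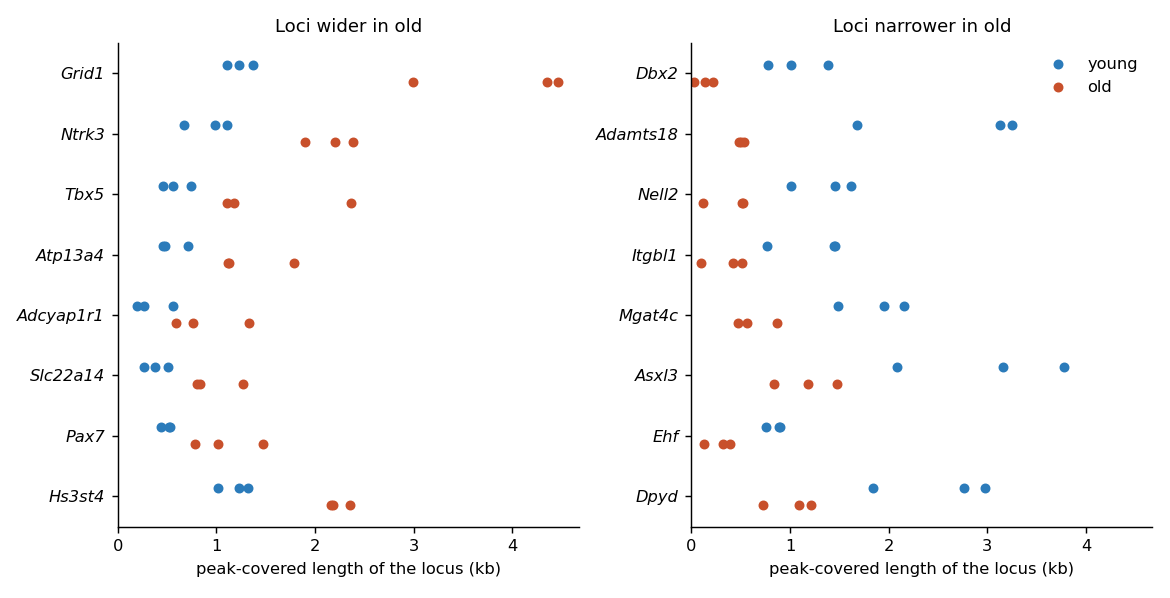
Length covered by deposited peaks in kb (horizontal axis, unscaled) at the 8 loci per direction with the largest changes; each point is 1 library, young blue and old orange. The 3 old points lie apart from the 3 young points in every row, as the naming rule required of the scaled values, and Grid1 reaches the highest old values.

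Because the lists differ in length, the same comparison was made on equal-length lists, the 50000 peaks per library with the highest −log10 q. These lists are equal in peak number only. They covered 27.2, 24.4 and 28.0 Mb in young and 28.0, 22.4 and 23.2 Mb in old replicates 1, 2 and 3. The −log10 q of their last peak was 8.86, 6.71 and 9.96 in young and 9.53, 5.72 and 6.47 in old. Young 1, young 3 and old 1 thus still had the widest coverage. On the equal-length lists the balance was the other way: 121 loci were wider and 63 narrower in old among 14395, beside 65 and 98 on the deposited lists. With a replicate block in the fit of the equal-length lists, 0 loci were wider and 0 narrower. Cd74, which codes for the MHC class II invariant chain (chromosome 18, 60803849 to 60812652), went from 1427 ± 140 bp in young to 404 ± 60.8 bp in old (SD, n = 3; log2 change -1.43, SE 0.14, adjusted p = 0.0156). On the deposited lists its log2 change was 0.05 (SE 0.11). Slc22a15 had 1231 ± 256 bp in young and 0 bp in each old library (adjusted p = 0.0158). Here 0 bp means that no peak ranked among the 50000 strongest, not that the deposited list had none. Dpp10, Marchf1, which codes for a ubiquitin ligase acting on MHC class II, Sinhcaf, Dusp16, a MAP kinase phosphatase gene, Kcna3, a potassium channel gene, and Tmod1 had log2 changes of -2.31 (SE 0.40), -2.09 (SE 0.38), -1.65 (SE 0.21), -1.54 (SE 0.21), -1.47 (SE 0.24) and -1.39 (SE 0.15). Their adjusted limma p lay between 0.0158 and 0.0470. None of the narrower loci named here, from Cd74 to Tmod1, was called on the deposited lists.

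Among the strongest peaks, the loci with most gain in old were B3galt1 (chromosome 2, 67565689 to 68122882), Hs3st4 and Nhs, which were at 0 bp in all young libraries and at 2062 ± 737, 1132 ± 108 and 1110 ± 189 bp in old (SD, n = 3; adjusted p = 0.0136, 0.0158 and 0.0169). On the deposited lists Hs3st4 had 1126 ± 34.4 bp in young, so 0 bp does not mean that its peaks were missing. Nhs was not called on those lists. Zan, Ppl, Serpine3, Fat2 and Psors1c2 had log2 changes of 2.22 (SE 0.32), 1.80 (SE 0.28), 1.76 (SE 0.15), 1.66 (SE 0.17) and 1.63 (SE 0.25), with adjusted limma p between 0.0136 and 0.0310. The repeat of the naming rule on equal-length lists was decided after the data were seen. Of the 163 loci called on the deposited lists, 99 passed the filter on the equal-length lists, 87 of them kept their direction and 18 were called there as well. In turn, the 121 and 63 loci called on the equal-length lists were all tested on the deposited lists, where 105 and 56 had the same direction. Their medians fell from 0.80 to 0.13 for the wider and from -0.86 to -0.15 for the narrower loci, and Zan, Ppl, Serpine3 and Psors1c2 had 0.35 (SE 0.10), 0.10 (SE 0.10), 0.39 (SE 0.12) and 0.20 (SE 0.16) there. Hs3st4, B3galt1, Fat2 and Stab2 were among the 11 wider in both, and Fat3, Fggy and Ppp1r9a among the 7 narrower in both. Of the loci named above for the largest changes on the deposited lists, from Grid1 to Dpyd, Hs3st4 alone was called in both. The rest were not called on the equal-length lists or lay below the filter there. Leaving out old replicate 1, 2 or 3, the equal-length lists gave 0, 5 and 5 wider and 3, 5 and 6 narrower loci. Leaving out young replicate 1, 2 or 3 gave 45, 59 and 85 wider and 6, 25 and 19 narrower loci. Of 115 such values for the 21 called loci named here, 72 no longer passed and 0 changed sign.

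The lists described in detail were chosen from the 43 after their values were seen. None of the 43 gene lists fixed in advance moved as a whole on the deposited lists (limma camera, smallest adjusted p = 0.10, with 3 lists at an unadjusted p under 0.05). The nearest was heme and iron handling, of which 15 of 19 tested loci had higher values in old (median log2 change 0.10, adjusted p = 0.10; adjusted p = 0.90 with an estimated correlation). At the preset correlation it passed limma camera without young replicate 2 (adjusted p = 0.0388), without old replicate 3 (adjusted p = 0.0414) and without the 500 bp filter (adjusted p = 0.0380). The estimated correlation was not run for these fits. With all 6 libraries, none of its members passed, whether adjusted over all genes or adjusted over the list alone; the smallest p belonged to Slc48a1, a heme transporter gene (log2 change 0.35, SE 0.12, adjusted p = 0.18), and Ftl1, the ferritin light chain gene (log2 change 0.26, SE 0.09, adjusted p = 0.20). On the equal-length lists the same list had a median of 0.11, with 13 of 17 loci higher (adjusted p = 0.052; adjusted p = 0.71 with an estimated correlation) and 3 wider and 1 narrower locus when adjusted over the list alone. Steap3, an iron reductase gene, had 0.55 (SE 0.11, adjusted p = 0.055), and Bach1, a heme-responsive repressor gene, had -0.32 (SE 0.09, adjusted p = 0.14). None of the 43 lists passed on the equal-length lists with all 6 libraries (limma camera, 6 at an unadjusted p under 0.05), but 5 passed without young replicate 3: macrophage identity, heme, extracellular matrix, osteoblast and Hox genes. Without old replicate 2, inflammatory chemokines, macrophage identity and extracellular matrix passed, without old replicate 3 heme and osteoblast genes, and without young replicate 1 inflammatory chemokines. With a replicate block these 6 lists passed. At an estimated correlation none of the 43 passed in any of these cases (limma camera, smallest adjusted p = 0.71, with all 6 libraries, where 2 had an unadjusted p under 0.05).

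Inflammatory chemokine loci had lower values in old among the strongest peaks, with 13 of 18 lower and a median log2 change of -0.15 (limma camera, adjusted p = 0.052; adjusted p = 0.71 with an estimated correlation). Ccl7, a monocyte-attracting chemokine gene, passed (log2 change -1.04, SE 0.14, adjusted p = 0.0219), and 2 members passed when adjusted over the list alone, the second being Ccl6 (-0.56, SE 0.11). On the deposited lists 0 of 22 passed, with Ccl7 at -0.25 (SE 0.10) and Ccl3 at -0.23 (SE 0.10), and Ccl6 had 0.15. Macrophage identity loci were likewise lower on the equal-length lists in 21 of 28 cases (median -0.14, camera, adjusted p = 0.052; adjusted p = 0.71 with an estimated correlation). Mertk, a receptor for apoptotic cells, was the 1 member past the threshold over all genes and adjusted over the list alone (log2 change -0.53, SE 0.09, adjusted p = 0.0347), and Clec4n had -0.43 (SE 0.11, adjusted p = 0.12). In the deposited lists this list had a median of 0.02 and no member passed; Ctss and Laptm5 had 0.34 (SE 0.10) and -0.30 (SE 0.12).

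Efferocytosis receptor genes went both ways among the strongest peaks. Mertk was narrower, whereas Axl, a related receptor, and Gas6, the ligand of both, were wider in old (log2 change 0.79, SE 0.09, and 0.73, SE 0.12; adjusted p = 0.0169 and 0.0318). With Stab2, 3 of the 24 loci were wider and 1 narrower, and 6 went each way when adjusted over the list alone; the list as a whole had an adjusted camera p of 0.965. On the deposited lists 1 of 26, Stab2, passed, and Cd36 had 0.23 (SE 0.08). Of the 21 loci for MHC class II and antigen presentation, Cd74 was the 1 that passed on the equal-length lists, where Cd86 had -0.62 (SE 0.19), and 0 passed on the deposited lists, where Ciita and Tap2 had -0.24 (SE 0.10) and -0.19 (SE 0.08). The limma camera test gave this list an adjusted p of 0.45 on the equal-length and 0.84 on the deposited lists.

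The extracellular matrix list had a median log2 change of 0.17 in the equal-length lists, with 16 of 21 loci higher in old (limma camera, adjusted p = 0.052; adjusted p = 0.71 with an estimated correlation), and of -0.09 in the deposited lists (adjusted p = 0.49). Col3a1 had 0.90 (SE 0.20) in the former and -0.18 (SE 0.09) in the latter, Fbn1 had 0.27 (SE 0.08) in the former, and Lox and Col6a1 had -0.32 (SE 0.09) and 0.27 (SE 0.08) in the latter. The osteoblast and chondrocyte list had 7 of 8 loci higher among the strongest peaks (median 0.25, camera, adjusted p = 0.052; adjusted p = 0.71 with an estimated correlation), with Alpl at 0.41 (SE 0.09) there and 0.18 (SE 0.08) on the deposited lists. The deposited lists gave it a median of -0.0072. The list's 1 called member on the deposited lists was Bglap, the osteocalcin gene, which was narrower in old (log2 change -0.53, SE 0.12, adjusted p = 0.0367), with its neighbour Bglap2 at -0.48 (SE 0.13); 3 of 17 loci were narrower when adjusted over the list alone. Hox genes, which share flanks within their clusters, had a median of 0.21 on the equal-length and -0.02 on the deposited lists (camera, adjusted p = 0.061 and 0.71; adjusted p = 0.71 and 0.92 with an estimated correlation).

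**Figure D3:**
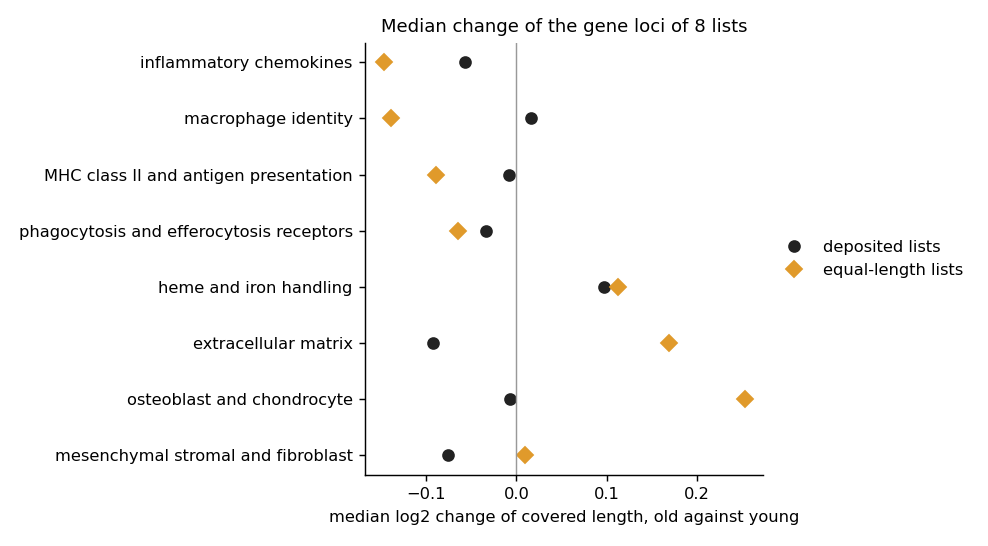
Median log2 change of covered length, old against young, over the tested loci of 8 gene lists; black circles are the deposited and orange diamonds the equal-length lists. Heme and iron handling lies near 0.1 in both, while the extracellular matrix list goes from -0.09 to 0.17.

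Peaks also covered loci of cell types other than macrophages. Covered length is summed over the whole locus and not adjusted for gene length, so these values do not rank the cell types. Macrophage identity loci had a median covered length of 2931 ± 117 bp in young and 3055 ± 164 bp in old, mesenchymal stromal and fibroblast loci 3210 ± 51.1 and 3126 ± 182 bp, B cell loci 1590 ± 29.5 and 1499 ± 107 bp, and neuronal loci taken as closed 1411 ± 160 and 1313 ± 292 bp (SD, n = 3). All protein-coding genes had a median of 1977 ± 19.9 and 1974 ± 3.18 bp. Runx2, the osteoblast transcription factor gene, was covered over 21734 ± 908 bp in young and 21648 ± 1430 bp in old on the deposited lists. Among the strongest 50000 peaks it went from 5963 ± 564 to 7487 ± 789 bp (log2 change 0.32, SE 0.10, adjusted p = 0.20, and adjusted p = 0.0386 over the list alone). On the deposited lists gene-end peaks were present at 94.4 ± 1.92% of macrophage identity genes in young and 93.3% in each old library, at 88.5% in each young library and 89.7 ± 2.22% in old of mesenchymal stromal genes, and at 71.0 ± 9.05% and 66.7 ± 6.64% of neuronal genes. All protein-coding genes had 71.5 ± 0.835% and 70.9 ± 1.10%, so neuronal genes were near the average there. Among the strongest 50000 peaks, gene-end peaks were present at 76.7 ± 3.33% of macrophage identity genes in young and 72.2 ± 1.92% in old, at 42.3 ± 7.69% and 51.3 ± 2.22% of mesenchymal stromal genes, and at 7.25 ± 2.51% and 5.80 ± 2.51% of neuronal genes, against 52.1 ± 0.509% and 51.9 ± 0.337% of all protein-coding genes. The exact permutation p of the age difference among the strongest peaks was 0.30 for macrophage and for mesenchymal genes. The mesenchymal list had 1 member called on the deposited lists, Fap, narrower in old (log2 change -0.47, SE 0.11, adjusted p = 0.0425), beside Pdgfra at 0.32 (SE 0.09). It had 1 called on the equal-length lists, S100a4, wider in old (0.61, SE 0.08, adjusted p = 0.0219), beside Kitl, the stem cell factor gene, at 1.57 (SE 0.29, adjusted p = 0.052). S100a4 is also a member of the monocyte list, so it does not stand for stromal cells alone.

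Merging the deposited peaks of all libraries gave 403801 regions on chromosomes 1 to 19 and X, of which 121253 were present in all 6 libraries. There were 5743 regions with a peak in all 3 young and no old library, and 2071 with a peak in all 3 old and no young library, so 73.5% of age-only regions were young-only. Both counts rose when a library was left out, to values that differed widely between libraries (given below). On equal-length lists the numbers were 1716 and 2177, and 44.1% were young-only. Of these 1716 and 2177, 1710 and 2169 had a deposited peak in all 3 libraries of the other age, so they mark peaks that were among the strongest at 1 age, not peaks missing at the other. For the age-only regions of the deposited lists, the median percentile of −log10 q, taken in the library where it was lowest, was 16.1 for young-only and 17.6 for old-only regions, where 100 is the top peak of a list; the lowest of 3 values is low by construction. The strongest young-only regions lay on chromosome 14 from 105737042 to 105737077, in no gene and 154870 bp from Spry2, on chromosome 1 from 161010434 to 161010791 within Zbtb37, and on chromosome 10 from 49049277 to 49049691, in no gene and 43989 bp from Grik2. The strongest old-only regions lay on chromosome 7 from 16094644 to 16094836 within Zfp541, on chromosome 16 from 78378550 to 78378872, 1369 bp from Btg3, and on chromosome 8 from 120482360 to 120482633 within Gse1. On the equal-length lists the strongest young-only regions lay on chromosome 17 from 31905788 to 31906297, 38472 bp from Hsf2bp, on chromosome 7 from 38189191 to 38190071 within 1600014C10Rik, and on chromosome 5 from 12079889 to 12080517, in no gene. Among the strongest old-only regions there were those on chromosome 19 from 42052880 to 42053690 within Hoga1 and on chromosome 4 from 43679423 to 43679932 within Tmem8b.

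**Figure D4:**
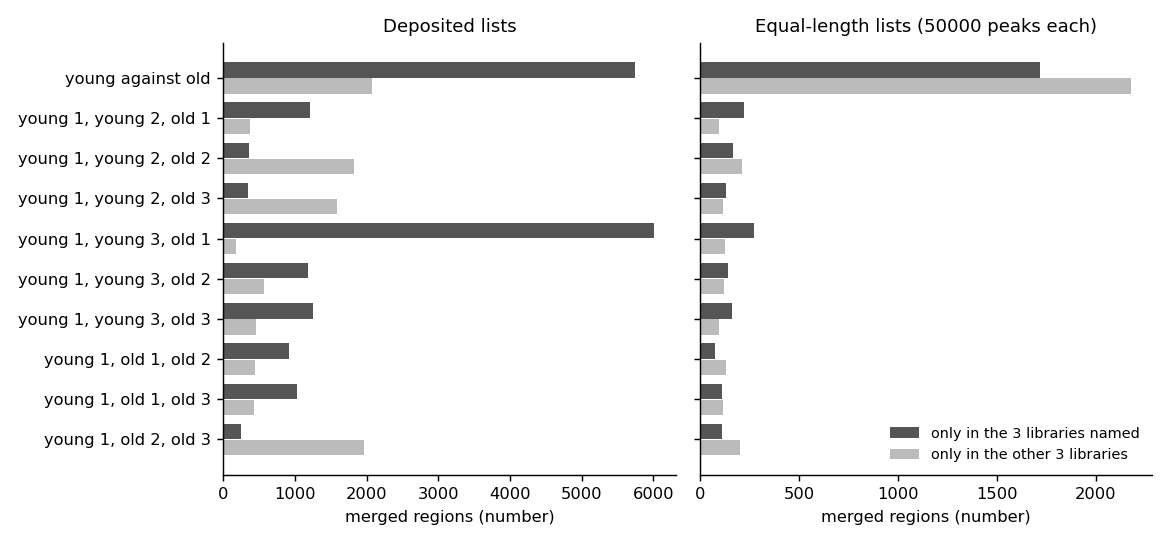
Number of merged regions present in 3 libraries and absent from the other 3, for each of the 10 ways to part the 6 libraries (rows name the side that holds young 1; dark bars are that side and light bars the other), with the top row young against old; the left and right panels have different scales. On the deposited lists the row of young 1, young 3 and old 1 reaches 6016, above the 5743 of the 3 young libraries, and on the equal-length lists no other row exceeds 271.

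Gene ends were read as a peak within 1 kb of either annotated end, since strand was not used here. Peaks there were present in all young and no old libraries for 51 genes and the other way for 20 genes on the deposited lists, and for 58 and 91 genes on the equal-length lists. The deposited counts rose without a library and fell under strict presence with lenient absence, as given below. Of these genes, 38 of 51 and 13 of 20 on the deposited lists and 54 of 58 and 85 of 91 on the equal-length lists had a merged region of that age alone at a gene end. At the others, the gene-end peaks belonged to regions that the other age also had, beyond 1 kb, or to different regions in different libraries. The genes counted as young-only whose peaks ranked highest were Epp13, Gpr31b, Dpt, which codes for the matrix protein dermatopontin, Glyatl3, Stambpl1 and Larp4, at percentiles from 84.9 to 29.4 in their weakest library. Epp13 and Stambpl1 had no young-only region: their young peaks lay in merged regions with peaks of old libraries. The genes counted as old-only were Atad1, Cdyl, Cacnb3, Cib4, Hephl1 and Atp13a4, at percentiles from 20.8 to 12.8, of which Cacnb3 and Cib4 had no old-only region. Among the strongest peaks, young-only gene ends were led by Supv3l1, Ccl28, Csf2rb2, a cytokine receptor subunit gene, Tbx6, Tnfsf14 and Armh4, at percentiles from 95.9 to 86.4. Supv3l1 had no young-only region, its peaks being part of a region that old libraries had as well. The old-only gene ends were led by Fsbp, C1qtnf1, Cdsn, Rgs8, Wt1, a transcription factor gene, and Galntl5, at percentiles from 88.3 to 87.3.

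The mean Jaccard index, shared over combined bases, was 0.614 within ages and 0.581 between ages on the deposited lists (one-sided exact permutation over 10 splits, p = 0.20). This difference, 0.0326, was below the 0.0337 of the split of young 1, young 3 and old 1 from the rest. On the equal-length lists the means were 0.701 and 0.635 (same exact permutation, p = 0.10, the smallest that these splits allow). No pair of libraries exceeded 0.734, so none was a copy of another. By place, 12.5 ± 0.644% of peaks in young and 12.7 ± 0.530% in old lay within 1 kb of a gene end, 48.3 ± 0.294% and 48.0 ± 0.431% in gene bodies, and 39.2 ± 0.359% and 39.3 ± 0.388% elsewhere (SD, n = 3; two-sided exact permutation p = 0.70 for gene ends).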

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

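In this part, the tests on neighbouring loci and on list length within each age were set before their results were seen; those on the split by list length, on the stromal list, on loci matched for covered length, on total covered length as a covariate and on other splits were chosen after. Peaks lay outside the compared chromosomes in every library: on chromosome Y a mean of 51.0 per young and 50 per old library, and on unplaced contigs a mean of 133 per young and 140 per old library. The Y peaks included Kdm5d, Uty, Ddx3y and Eif2s3y in all 6 libraries, and the labels give no sex.

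The deposited lists held more young-only than old-only regions (5743 against 2071). The 3 lists with the most peaks, young 1, young 3 and old 1, held 6016 regions that the other 3 lacked, more than the 3 young lists. A candidate explanation is therefore that libraries with more signal call more peaks. Age stays open, untested: the real split gave 7814 age-only regions in total and the highest other split, which is that same one, 6193, and 10 splits are too few for a share under 0.05. With peaks of −log10 q of 2 or more, the real split gave 6401 regions and that split 5071, and with 5 or more 2704 and 4737, so that there the libraries part more by list length than by age.

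On the equal-length lists, macrophage and inflammatory chemokine loci had lower and matrix, osteoblast and heme loci higher values in old, but none of these 5 lists passed limma camera with all 6 libraries, with an adjusted p = 0.052 at the preset and an adjusted p = 0.71 at an estimated correlation; of 43 lists, 5 passed without young replicate 3, 3 without old replicate 2, 2 without old replicate 3, 1 without young replicate 1 and 6 with a replicate block, but 0 in each of these cases at an estimated correlation. Short minus long lists moved as old minus young within both ages for 0 of the 5 gene lists and the opposite way within both ages for 3. This argues against library signal, but each age has a single library on one side, which the bound set beforehand did not allow for, so it stays open. More stromal cells in the old cultures may also give such values: the mesenchymal stromal and fibroblast list had a median log2 change of 0.01 (limma camera, adjusted p = 0.45), with 4 members wider and 0 narrower when adjusted over the list alone (S100a4, Kitl, Prrx1 and Col3a1), but Col1a1 at 0.17 (SE 0.20) and Col1a2 at -0.09 (SE 0.15). The cells were typed as F4/80+CD169+, and 5 of the 26 genes of this list are also in the extracellular matrix list. S100a4 is also in the monocyte list. Stromal cells and an age effect within macrophages both stay open.

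The called gene loci of the deposited lists were long. For the called loci as a set, a change of covered length over a wider segment is argued against by the nearest neighbours that share no base with them. For 158 of the 163 loci these had a median log2 change of 0.0081 (bootstrap 95% interval -0.02 to 0.05) in the direction of the call, and the called loci 0.53. A median does not exclude such a change at single loci. Covered length need not follow copy number, so a difference in copy number stays open. Dbx2 and its neighbour Nell2 were both called narrower in old (log2 change -1.87 and -1.38). That called loci are long merely because they hold more covered bases is argued against by uncalled loci matched on mean covered length. Their median gene length was 25.0 kb (19.9 to 31.1 kb in 95% of 1000 draws) against 109 kb for called loci. These values are lengths, so they do not show whether long loci vary less at equal covered length, which stays open. Library signal stays open as a cause. With total covered length as a covariate, 163 of the 163 loci kept their direction. Their median log2 change in the direction of the call went from 0.54 to 0.51 (bootstrap 95% interval 0.48 to 0.54, median SE 0.11 in both fits). The 125 that no longer passed went from 0.50 to 0.46 in a fit with 1 residual degree of freedom fewer. The covariate cannot decide this, since the loci were called for their age difference in these same data. At all 163 the old values, those of old 1 with its long list included, lay apart from the young values. With 3 libraries per age a call all but requires this, so it does not decide the question either. Values had also been divided by the library's sum before the fit. An effect of age on long genes may remain, untested: the real split called 163 loci (2164 at an unadjusted p under 0.05) and the highest other split, young 1, young 3 and old 1, 18 (2362), and on the equal-length lists the real split 184 (2136) and the others 0 (at most 926); 10 splits are too few for a share under 0.05.

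Further counts were set beside other splits, with 10 splits again too few for a share under 0.05. Age-only regions of the equal-length lists numbered 3893 and at most 396 in another split. Genes with age-only gene-end peaks numbered 71 on the deposited lists, where the split of young 1, young 3 and old 1 from the rest gave 77, so that 2 splits reached the real count (with −log10 q of 2 or more 113 against 75 in the real split, with 5 or more 242 against 66), and 149 against at most 33 on the equal-length lists.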

How the results depend on the processing

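The covariate, the 5 kb windows, and the block, left-out libraries and estimated correlation on equal-length lists were chosen after seeing the data; other settings were planned. Motif content was not run, since no genome sequence was used, nor was the planned gene-start locus, since strand was not used. No value exists for peaks per library on equal-length lists, nor for Cxcl13 at −log10 q of 5 or more or on equal-length lists, where it has no peak. The cause of a change was not tested, except that leaving out a library lets more regions meet the age-only criteria and that the covariate takes 1 residual degree of freedom. Read depth is unknown and limits what absence of a peak means. The pairwise overlap and the difference in peaks per library kept their direction in all settings run; with 3 libraries against 3, their p could not have passed the threshold in any.

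At −log10 q of 2 or more, 11 genes had old-only gene ends, Adgre1 had -0.23 and Cxcr5 0.078. At 5 or more, there were 2002 young-only and 702 old-only regions, 12 genes with old-only ends, and 3 wider and 6 narrower loci; log2 changes were -0.27 for Adgre1, -0.049 for Cd36, -0.19 for Ctss, 0.019 for Lox, -0.038 for Siglec1 and -0.017 for Slc48a1. Equal-length lists gave 1716 young-only regions, 91 genes with old-only ends, 121 wider and 63 narrower loci, and -0.087 for Cd36, -0.48 for Ctss and -0.73 for Siglec1. In turn, loci read first on equal-length lists had 0.15 for Ccl6, 0.048 for Cd74, -0.18 for Col3a1, -0.031 for Fbn1 and 0.11 for Siglec1 on the deposited lists. With strict presence and lenient absence there were 1632 young-only and 410 old-only regions, and 11 genes with young-only and 0 with old-only ends; within 100 bp, 5 genes had old-only ends. Without scaling, 2 loci were wider and 13 narrower, with Siglec1 at -0.045. No filter gave 0 wider and 4 narrower loci and 1 passing gene list. Windows of 5 kb around gene ends gave 5 wider and 9 narrower loci and 0.11 for Cxcr5. With the covariate, 32 were wider and 19 narrower, with Cxcl13 at 0.035 and Cxcr5 at 0.10.

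The labels do not say whether replicate numbers pair the libraries. Across genes of the deposited lists, young and old libraries of 1 number correlated at r = 0.14, 0.13 and -0.16, and young 3 with old 1 at 0.26. On the equal-length lists, libraries of 1 number correlated at 0.051, 0.051 and 0.029. These were the highest values there but all were small, so pairing stays open. A replicate block gave 98 wider and 178 narrower loci. On equal-length lists it gave 0 and 0, with 6 passing gene lists at the preset and 0 at an estimated correlation.

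Leaving out 1 library gave 7121 to 15173 young-only regions (highest without young replicate 2) and 2550 to 5324 old-only regions (highest without old replicate 2), 64 to 166 and 27 to 60 genes with young-only and old-only ends (highest without old replicates 1 and 3), and, for young-only regions, equal-length lists, 2147 to 2817 (highest without old replicate 1). It gave 16 to 92 wider and 15 to 260 narrower loci (lowest without young replicate 1, highest without old replicate 1), and 0 to 85 and 3 to 25 on equal-length lists (lowest without old replicate 1, highest without young replicates 3 and 2). Passing gene lists were 0 to 1, and 0 to 5 on equal-length lists (5 without young replicate 3). At an estimated correlation, 0 passed in each of these fits on equal-length lists. In the genomic distribution, the gene-end share differed by -0.037 to 0.59 points (lowest without old replicate 3), Cxcl13 had -0.39 to 0.13, and Cxcr5 -0.12 to 0.065, or -0.14 to 0.043 on equal-length lists. For the 19 called loci named on the deposited lists, 50 of 142 values under other settings and 31 of 110 without a library no longer passed, and 0 changed sign; on equal-length lists 39 of 42 (1 of them, Cd74, with the other sign) and 72 of 115 for 21 loci. These are loci named by the rule or leading a described list; Cdh11, named below, is not among them.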

Other observations

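Further loci were called on the equal-length lists; these were picked from the called loci after their values were seen. Narrower in old were Hhex, a homeobox transcription factor gene (log2 change -1.12, SE 0.18, adjusted p = 0.0321), Mrc1, the mannose receptor gene (-1.03, SE 0.16, adjusted p = 0.0318), Trem1, a receptor that amplifies inflammatory signals (-0.82, SE 0.13, adjusted p = 0.0302), and Tfec, a transcription factor gene (-0.74, SE 0.13, adjusted p = 0.0401). Wider in old were Scara5, a ferritin receptor gene (1.56, SE 0.21, adjusted p = 0.0231), Cd200, the gene of a ligand that restrains myeloid cells (1.43, SE 0.20, adjusted p = 0.0244), and Cdh11, a cadherin gene (1.10, SE 0.17, adjusted p = 0.0284). In each case the 3 old values lay on one side of the 3 young values, as at all 184 loci called on these lists. Scara5 was called on the deposited lists too (0.44, SE 0.08, adjusted p = 0.0113), Mrc1 and Hhex had -0.26 (SE 0.07) and -0.25 (SE 0.09), Trem1 and Tfec had -0.01 (SE 0.13) and -0.06 (SE 0.13), Cd200 had 0.18 (SE 0.11), and Cdh11 had -0.40 (SE 0.10), the other sign.

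Among lists not described above, 0 passed limma camera on either kind of list; the interferon response list had medians of -0.01 and -0.04 on the deposited and equal-length lists, the senescence list 0.01 and -0.05, and the B-cell support list -0.08 and 0.07, with 0 members called over all genes in these 3 lists. The strongest peak of every library lay on chromosome 1 from 24612627, and no library had peaks on the mitochondrial chromosome. Of the 163 loci called on the deposited lists, 87 of the 99 measured on the equal-length lists had the same direction; the strongest peaks are part of the deposited lists, so this is no independent test, and a test of weak peaks as an explanation built on it was set aside as void.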
